A study of Mus musculus with 32 samples.

How the data were processed

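Per the labels, liver RNA of 32 male F1 C57BL/6J mice was hybridised to Agilent one-colour (Cy3) arrays, 1 array per mouse. Mice were on a normal diet or a Western diet for 16 weeks and were sampled at 21 weeks of age, with pellets without E171 or with E171 at a target of 10 mg per kg of body weight per day. F0 females received the same pellets from before mating, and their F1 offspring stayed on the treatment of the mother; the diet was changed at adulthood. The group labels name a Western diet and the treatment protocol a high-fat diet; the name of the group labels is used. This gives 4 groups of 8 mice: normal diet control, normal diet E171, Western diet control and Western diet E171. Litter and time of day are not given in the labels, so all tests take the 8 mice of a group as independent, which littermates need not be.

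The deposited raw files are Feature Extraction outputs of 62976 spots per array with processed and raw Cy3 intensity values; per the submitters' processing notes they were made with Agilent Feature Extraction 10.10.1.1, and the further processing named limma. Per the file headers the processed signal is a background-corrected intensity on the linear scale. A deposited value table holds log2 values of 36695 probes. Its values were checked against the raw files: the lowest correlation of an array with the log2 median signal was 0.9996, and its columns have the same mean within each group but a different mean in each group (7.82, 7.81, 7.85 and 7.84 for normal diet control, normal diet E171, Western diet control and Western diet E171). It lay closer to a quantile normalization over all arrays (mean absolute difference 0.0162) than to one within each group (0.0599). The steps behind it are not given in the sources used here, so it serves as an alternative.

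For the main analysis, log2 of the processed signal was averaged over replicate spots (300 probes have them) after spots marked as outliers by Feature Extraction (42 to 91 per array) were left out, and the 75th percentile of each array was subtracted. Control spots were left out, which leaves 56605 probes. A probe was kept if Feature Extraction called it well above background on at least 6 of the 8 arrays of at least 1 group, which holds for 35777 probes. Gene names were matched by accession (32994 probes), symbol (10224) or synonym (520) to a mouse RefSeq gene table, or taken from the file (2574); 10293 probes have no name. The probe with the highest mean signal stood for each gene, giving 23644 tested genes, 18247 with a name and 5397 known by probe only. Of these, 7750 had several kept probes, whose lowest and highest values are given for the named genes where they differ in sign or size. Positions are those of the probe in the mm9 build named in the file headers.

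Arrays gave 32163 to 37261 probes well above background, with a 75th percentile of 249 to 489 intensity units, 0 saturated spots and a median coefficient of variation of 8.59 to 10.2% between replicate spots of a probe. The 75th percentile averaged 367, 356, 430 and 403 for normal diet control, normal diet E171, Western diet control and Western diet E171. The arrays lay on 4 slides, each with 2 mice of every group, and slide and scan coincide. Correlations of arrays within a group ran from 0.981 to 0.996, and no arrays were identical.

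All 32 arrays were fitted with limma 3.58.1 in R 4.3.3, with the package data.table in version 1.17.8 for reading, and 1 mean per group and without a block. Contrasts were Western against normal diet in controls and in E171 mice, E171 against control on each diet and averaged over both, and the interaction of E171 and diet. P values are two-sided moderated t tests, adjusted over all genes of a contrast by the method of Benjamini and Hochberg, with a threshold of 0.05. A fold against a group in which the probe was well above background on 0 of 8 arrays is given as a lower bound against the background limit of that group. Where it was so on some arrays only, the measured difference is given with the number of arrays.

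In total 39 lists were fixed (27 of pathways and 12 of cell types) and tested with camera with a preset correlation of 0.01, adjusted over the lists. The pathway lists cover SREBP2 targets, fatty acid oxidation and PPARα targets, lipid droplet and lipid uptake, LXR targets, lipogenesis, bile acids, xenobiotic cytochromes P450, NRF2 targets, antioxidant enzymes, metal handling, the unfolded protein and integrated stress response, glucose metabolism, amino acid and urea metabolism, oxidative phosphorylation, inflammatory cytokines and chemokines, acute phase proteins, interferon-stimulated genes, MHC class II, fibrosis, lysosome, cell cycle, p53 targets, immediate early genes, the circadian clock, glucocorticoid targets, and male-biased and female-biased liver genes. The cell types are hepatocyte, Kupffer cell and macrophage, lipid-associated macrophage, neutrophil, T and NK cell, B cell, stellate cell, endothelial cell, cholangiocyte, erythroid cell, adipocyte and exocrine pancreas. Some genes stand in more than 1 list, such as Spp1 (fibrosis, lipid-associated macrophage, cholangiocyte), Cyp7b1 and Slco1a1 (bile acids, male-biased), Lpin1 (lipogenesis, glucocorticoid targets) and Per1 (clock, glucocorticoid targets).

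Genes named in the text follow a rule. For each contrast these are the 8 largest rises and 8 largest falls among passing genes with a symbol, taken by the fitted difference also where the text gives a bound; where under 5 genes pass, all of them and the 3 smallest p values in each direction. Added to these are up to 4 members with the smallest p of each passing list, the member with the largest absolute difference of each described list, and, for E171, Mt1, Mt2, Hmox1, Nqo1, Tnf, Il1b, Ccl2, Col1a1 and Saa1 whatever their p. Some genes that meet the rule are not reported here and were left out of the search for single mice far from their group. Groups, contrasts, tests, lists, the rule and the first set of other settings were fixed before the data were examined. Nfil3 and the other clock genes outside these rules were chosen after their values were seen.

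The steps were tested on simulated data with 200 of 23644 genes changed between control and E171 on the Western diet and noise drawn independently for each gene. Of the changed genes, 55.2% of 67 were called at a log2 difference of 0.5, 92.5% of 67 at 1 and 100% of 66 at 2, with 0 of the wrong sign; 7 unchanged genes were called, and 0 genes in a contrast that had not been moved. A list moved by 0.5 had an adjusted p of 1.13e-08, and 0 other lists passed. Since noise was independent between genes, the simulation does not test how correlated genes affect camera.

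Other settings fixed in advance were normexp background correction of the mean signal with an offset of 50, quantile normalization, the deposited value table (23596 genes), no filter on dim probes (37488 genes), probes well above background on all arrays (20149 genes), slide as a block, replicate number as a block, array weights, an intensity trend in the prior, every probe tested on its own, a fit of only the groups of the contrast, a fold change of at least 1.5, an estimated correlation in camera, and the rotation test fry. Settings added after seeing the data were quantile normalization of the median signal over all arrays and within each group, a fit without the 2 arrays of lowest correlation, and fits with 1 of 4 covariates: array intensity, the clock score, the first component of the residuals, and the place of each mouse on the main mouse to mouse axis. Random splits of the mice, 100 per contrast with the real one included, kept the group sizes.

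Scores per mouse are means of list members after centring each gene, compared by exact two-sided tests over all 12870 splits of 16 mice and adjusted by Benjamini and Hochberg over 16 tests for E171 and 22 for diet. The clock score is the mean of 10 day genes minus the mean of 5 night genes, written down after the values had been seen. Left out were control spots, outlier spots and dim probes; 27 values were missing among kept genes. Litter, time of sampling and tissue measurements other than RNA were not used here.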

Results

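The labels ask whether diet aggravates the response of the liver to E171, a food-grade titanium dioxide additive. Liver RNA was measured on 1 one-colour array per mouse in 32 male F1 C57BL/6J mice, 8 per group, kept on a normal or a Western diet with or without E171 in the pellets. Differences are log2 ratios between groups of 8 mice, given with the standard error (SE), and adjusted p values come from two-sided moderated t tests in limma over 23644 genes. Lists of genes were tested with camera, and counts of list members are over all tested genes unless they are said to be adjusted over the list alone. The largest rises and falls named are those among genes with a symbol.

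On the Western diet, control livers held more mRNA of lipid droplet, macrophage and scar genes, and less of genes for cholesterol synthesis, amino acid breakdown and the male pattern of liver metabolism. With an estimated correlation only the lipid droplet list among these passed (adjusted p = 0.0117), against adjusted p = 0.129 for lipid-associated macrophage, adjusted p = 0.454 for Kupffer cell, adjusted p = 0.129 for fibrosis, adjusted p = 0.252 for SREBP2, adjusted p = 0.502 for amino acid and adjusted p = 0.454 for male-biased genes. Cidea and Cidec, whose proteins sit on lipid droplets and promote their fusion, rose by 6.48 (SE 0.68, adjusted p = 7.87e-09) and 6.37 (SE 0.23, adjusted p = 9.31e-19). Gpnmb, a membrane glycoprotein of lipid-laden macrophages, was at least 51.0-fold higher, a lower bound because its probe (chromosome 6, 49006386 to 49006445, mm9) was not well above background on the normal diet. Hsd3b5, a steroid dehydrogenase typical of the male mouse liver, fell by 6.86 (SE 1.02, adjusted p = 2.5e-06), with an SD of 2.91 among the Western-diet controls against 0.38 on the normal diet. In all, 11183 genes passed, 4385 higher and 6798 lower, of which 1289 were at least 2-fold higher and 417 at least 2-fold lower.

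Other large rises were those of Ly6d, a surface protein anchored by a lipid (6.46), Mmp12, the macrophage elastase (5.62, with 3.73 to 5.62 over its 3 probes), and Sdcbp2, a PDZ domain protein (5.52). Tinag, a basement membrane antigen (at least 14.8-fold higher), and Themis, a protein of T cell development (at least 12.3-fold higher), are known by a bound only and have no rank. The largest falls after Hsd3b5 were in Adgrf1, an adhesion G protein-coupled receptor (-6.01), and Moxd1, a monooxygenase-like protein (-3.77). Next came Tff3, a trefoil peptide (-3.56), Susd4, a complement regulator (-3.25), Cxcl13, a B cell chemokine (-3.16), and Cnmd, chondromodulin (-3.08). Wif1, a secreted Wnt inhibitor, was at least 3.53-fold lower, also without a rank. In the dimmer group the probe was well above background on 2 of 8 arrays for Mmp12, 4 for Sdcbp2, 3 for Adgrf1, 2 for Moxd1 (6 in the other group), 6 for Cxcl13 and 7 for Cnmd.

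**Figure D1:**
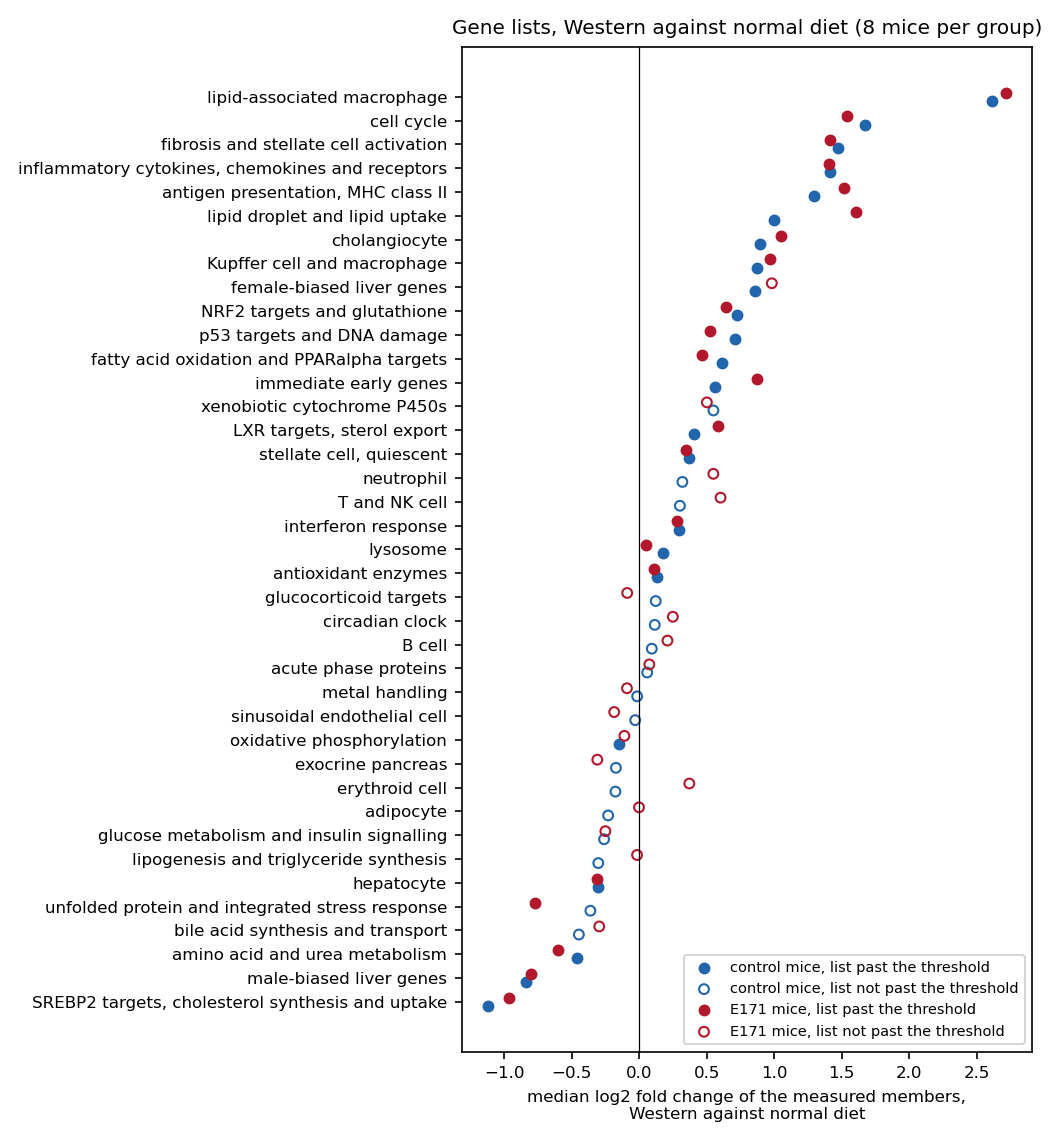
Median log2 difference between Western-diet and normal-diet mice over the members of each gene list (x axis), for control mice (blue) and E171 mice (red), 8 mice per group. Filled points are lists past the test in camera with the preset correlation, and open points are lists that did not pass; oxidative phosphorylation turned positive in controls under other scalings.

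Lipid genes moved in opposite directions according to their function. In the lipid droplet and lipid uptake list, 15 of 17 measured members rose and 0 fell (adjusted p = 1.41e-12, adjusted p = 0.0117 with an estimated correlation). Among them were Plin4, a droplet coat protein (3.58), Cd36, a fatty acid transporter (2.93), and Apoa4, an apolipoprotein (2.82). Targets of SREBP2, the activator of cholesterol synthesis, fell in 22 of 23 cases and rose in 1. Examples are Sqle, squalene epoxidase (-2.58), Idi1, isopentenyl diphosphate isomerase (-1.92), Cyp51, lanosterol demethylase (-1.65), Tm7sf2, a sterol reductase (-1.39), and Stard4, a cholesterol carrier (-1.12). SREBP2 targets as a list had an adjusted p of 1.87e-08 (adjusted p = 0.252 with an estimated correlation). Genes of fatty acid oxidation and other PPARα targets rose in 17 of 26 cases and fell in 0, or 19 and 1 when adjusted over the list alone. They included Acot2, a mitochondrial thioesterase (2.27), Acaa1b, a peroxisomal thiolase (1.34), Ehhadh, a peroxisomal hydratase and dehydrogenase (1.07), and Pex11a, a factor of peroxisome division (0.92). This oxidation list had an adjusted p of 3.25e-06 (adjusted p = 0.268 with an estimated correlation). LXR targets of sterol export rose in 6 of 10 cases and fell in 1, with Abcg1 (1.26), Abcg5 (1.24) and Abcg8 (0.88), all sterol exporters, and Lpcat3, a phospholipid acyltransferase (0.43). The LXR list had an adjusted p of 0.0141 (adjusted p = 0.107 with an estimated correlation).

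NRF2 targets rose in 14 of 20 cases and fell in 3. Examples were Gsta2, a glutathione transferase (2.60), Nqo1, a quinone reductase (1.81), Srxn1, sulfiredoxin (1.48), and Ephx1, microsomal epoxide hydrolase (1.0). The NRF2 list had an adjusted p of 4.82e-06 (adjusted p = 0.107 with an estimated correlation). The antioxidant list had 7 of 15 members higher and 3 lower, or 7 and 4 when adjusted over the list alone. The higher ones include the uncoupling protein Ucp2 (1.21), the glutathione peroxidases Gpx3 (1.05) and Gpx4 (0.90) and the extracellular superoxide dismutase Sod3 (0.50). The antioxidant list had an adjusted p of 0.0242 (adjusted p = 0.268 with an estimated correlation). Amino acid and urea genes fell in 15 of 20 cases and rose in 0, or 16 lower when adjusted over the list alone. These were led by Cps1, the entry enzyme of the urea cycle (-1.12), Hal, histidine ammonia-lyase (-1.12), Gnmt, glycine methyltransferase (-0.96), Cbs, cystathionine beta-synthase (-0.66), and Arg1, arginase (-0.49). The amino acid list had an adjusted p of 0.00215 (adjusted p = 0.502 with an estimated correlation). In the oxidative phosphorylation list 12 of 25 members were lower and 0 higher, or 13 lower when adjusted over the list alone. Named members are Ndufb5 (-0.35) and Ndufb9 (-0.34) of complex I and Atp5o (-0.30) and Atp5j (-0.27) of ATP synthase. Oxidative phosphorylation had an adjusted p of 0.00959 (adjusted p = 0.619 with an estimated correlation). The median of this list, -0.15, turned positive under other scalings (0.0629 with quantile normalization), and Ndufb9, Atp5o and Atp5j each lost their call in 4 settings.

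Genes of inflammation, scar formation and dividing cells rose together. In the inflammatory list 15 of 22 members rose and 1 fell. They were led by the chemokines Ccl3 (3.63), Ccl4 (3.03) and Ccl7 (3.01), with the chemokine receptor Ccr2 (2.22) and the adhesion molecule Vcam1 (1.58). Lcn2, a siderophore-binding protein that also rose (3.90), belongs to the acute phase list, which did not pass. The inflammatory list had an adjusted p of 5.51e-09 (adjusted p = 0.107 with an estimated correlation). All 20 measured fibrosis genes rose, among them Mmp13, a collagenase (4.01), Col1a1 (3.02) and Col3a1 (2.23), fibrillar collagens, and Lox, a collagen cross-linking enzyme (2.58). The fibrosis list had an adjusted p of 1.52e-14 (adjusted p = 0.129 with an estimated correlation). Cell cycle genes rose in 17 of 21 cases and fell in 0, or 18 higher when adjusted over the list alone. Rises were seen in Cdk1, the mitotic kinase (3.25), Cdc20, an activator of the anaphase-promoting complex (3.16), Plk1, polo-like kinase (2.62), Birc5, survivin (2.48), and Ccnb2, cyclin B2 (2.42). Cell cycle genes as a list had an adjusted p of 3.67e-15 (adjusted p = 0.107 with an estimated correlation). Targets of p53 rose in 15 of 17 cases and fell in 0. Members include Eda2r, a death receptor (2.92), Phlda3, an Akt inhibitor (2.02), Btg2, an antiproliferative factor (1.49), and Zmat3, an RNA-binding protein (0.71). The p53 list had an adjusted p of 1.06e-08 (adjusted p = 0.00772 with an estimated correlation). MHC class II genes rose in all 8 cases, with H2-Aa (1.47), H2-Eb1 (1.39), the protease Ctss (1.39), H2-DMb1 (1.30) and their activator Ciita (1.20). The class II list had an adjusted p of 1.07e-05 (adjusted p = 0.252 with an estimated correlation). Interferon-stimulated genes rose in 12 of 26 cases and fell in 1, with Mx1 (1.08), Ifit2 (1.02), Oasl2 (1.0) and Oas2 (0.92), all antiviral effectors. The interferon list had an adjusted p of 0.00215 (adjusted p = 0.539 with an estimated correlation). Lysosome genes rose in 8 of 17 cases and fell in 2, or 3 when adjusted over the list alone, with the proton pump subunit Atp6v0d2 (1.61) and the hexosaminidase Hexa (1.09). The lysosome list had an adjusted p of 0.00524 (adjusted p = 0.127 with an estimated correlation). Immediate early genes rose in 6 of 13 cases and fell in 2, or 7 and 2 when adjusted over the list alone, with the transcription factors Egr2 (3.31), Klf6 (1.79) and Jun (1.15) and the stress protein Ier3 (1.01). The immediate early list had an adjusted p of 0.00216 (adjusted p = 0.129 with an estimated correlation). Of the genes named here, the probe was well above background on 4 of 8 normal-diet arrays for Ccl3, 2 for Mmp13, 6 for Lox, 1 for Cdk1 and 3 for Eda2r.

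Markers of several cell types moved with these groups. Markers of lipid-associated macrophages rose in 9 of 11 cases and fell in 1, with the lipid receptor Trem2 (3.98) and the integrin Itgax (2.80, and 0.02 with its other probe). The lipid-associated macrophage list had an adjusted p of 5.63e-08 (adjusted p = 0.129 with an estimated correlation). Kupffer cell and macrophage markers rose in 10 of 14 cases and fell in 1. Higher were Lyz2, lysozyme (1.51), Cd68, a lysosomal glycoprotein (1.44), Cybb, an NADPH oxidase subunit (1.18), and Cd5l, a secreted scavenger protein (1.11), and lower was the scavenger receptor Cd163 (-1.76). Kupffer cell markers as a list had an adjusted p of 0.00112 (adjusted p = 0.454 with an estimated correlation). Stellate cell markers rose in 5 of 10 cases and fell in 1, or 6 and 1 when adjusted over the list alone. Named members are the growth factor receptor Pdgfrb (1.07), the retinol-esterifying enzyme Lrat (0.76) and the proteoglycan Dcn (0.49) against the matrix protein Ecm1 (-0.59). Stellate cell markers as a list had an adjusted p of 0.016 (adjusted p = 0.343 with an estimated correlation). Cholangiocyte markers rose in 4 of 9 cases and fell in 1, or 5 and 1 when adjusted over the list alone. The named ones are osteopontin, Spp1 (1.43), the adhesion molecule Epcam (1.09), the keratin Krt7 (1.04) and the chloride channel Cftr (0.92). Cholangiocyte markers as a list had an adjusted p of 0.0391 (adjusted p = 0.586 with an estimated correlation). Hepatocyte markers fell in 10 of 11 cases and rose in 0, with fibrinogen Fgb (-0.77), Apoa1, the main HDL protein (-0.45), and fetuin-A, Ahsg (-0.37). Ahsg lost its call in 3 settings, all of them other scalings, and Apoa1, Krt7 and Epcam in 1 each. Hepatocyte markers as a list had an adjusted p of 0.00265 (adjusted p = 0.432 with an estimated correlation). Male-biased liver genes fell in 13 of 17 cases and rose in 0, with the organic anion carrier Slco1a1 (-2.76), the hydroxylase Cyp7b1 (-2.29), the elongase Elovl3 (-1.94) and Cyp2d9 (-1.34; adjusted p = 0.000545, adjusted p = 0.454 with an estimated correlation). Female-biased genes rose in 6 of 9 cases and fell in 1, with Cyp2b13 (3.14; well above background on 3 of 8 normal-diet arrays), Cyp3a16 (0.99) and Cyp3a41a (0.86), cytochromes P450, against the prolactin receptor Prlr (-1.0). The female-biased list had an adjusted p of 0.0153 (adjusted p = 0.223 with an estimated correlation).

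The remaining lists did not pass in controls. They include lipogenesis (6 of 20 higher, 3 lower; adjusted p = 0.476; largest member Mogat1, a monoacylglycerol acyltransferase, 3.04), and bile acids (5 of 21 higher, 14 lower; adjusted p = 0.154). Neither did xenobiotic cytochromes P450 (12 of 22 higher, 8 lower; adjusted p = 0.202; Cyp2b10 3.31) or metal handling (6 of 16 higher, 6 lower; adjusted p = 0.596; hepcidin, Hamp, -2.30) pass. The unfolded protein and integrated stress response was short of it too (3 of 20 higher, 9 lower, or 4 and 11 when adjusted over the list alone; adjusted p = 0.505; Atf3 2.29). Glucose metabolism (0 of 20 higher, 10 lower; adjusted p = 0.152; glucose-6-phosphatase, G6pc, -1.18) and acute phase proteins (5 of 19 higher, 7 lower, or 5 and 8 when adjusted over the list alone; adjusted p = 0.992) did not pass. Nor did the circadian clock (5 of 16 higher, 6 lower; adjusted p = 0.702; the clock output factor Dbp 2.39) or glucocorticoid targets (1 of 10 higher, 1 lower; adjusted p = 0.504; Cebpd 0.75). Among cell types, neutrophil (2 of 9 higher, 1 lower; adjusted p = 0.319; Cxcr2 1.52, well above background on 3 of 8 normal-diet arrays), T and NK cell (4 of 14 higher, 2 lower; adjusted p = 0.117; Cd8a 1.74, on 1 of 8, and on 6 of 8 on the Western diet) and B cell markers (1 of 8 higher, 1 lower; adjusted p = 0.471; Cd79b 0.57) did not pass. The same holds for endothelial (2 of 15 higher, 4 lower; adjusted p = 0.885; Lyve1 1.07) and erythroid markers (0 of 7 higher, 0 lower; adjusted p = 0.763; Slc4a1 -0.28). Markers of adipocytes (2 of 6 higher, 3 lower; adjusted p = 0.885; Cfd 2.80) and of the exocrine pancreas (0 of 6 higher, 2 lower; adjusted p = 0.21; Cela1 -1.52, and 1.09 with its other probe) did not pass.

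The direction of the 11183 calls was the same on all 4 slides for 9836 genes, which is no test since they were called on the same mice. Of the called genes 2356 had no overlap between the groups (chance gives 0.0155% of genes). Over all genes the median difference was -0.10, and the share of calls that were higher depended on the scaling (39.2% here, 54.5% with the deposited table, 81.8% when each group was quantile normalized on its own).

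In mice given E171, the Western diet also went with higher mRNA of lipid droplet, macrophage and scar genes and lower mRNA of cholesterol synthesis genes. Of the 22 lists that passed, only lipid droplet did so with an estimated correlation (adjusted p = 0.0245). Markers of lipid-associated macrophages rose in 9 of 11 cases and fell in 1 (adjusted p = 7.57e-07, adjusted p = 0.203 with an estimated correlation), and those of Kupffer cells in 10 of 14 and 1 (adjusted p = 0.00141, adjusted p = 0.464 with an estimated correlation). Cidea rose by 8.64 (SE 0.68, adjusted p = 2.41e-11), Cidec by 7.24 (adjusted p = 2.15e-20), and Gpnmb was at least 47.6-fold higher. Ly6d (6.12), the adipokine and complement factor D gene Cfd (5.92), Flacc1 (5.65) and Sdcbp2 (5.54) rose too, and Mmp12 was at least 27.8-fold higher. The probe was well above background on 2 of 8 normal-diet arrays for Flacc1 and 3 for Sdcbp2, and on 2 of 8 Western-diet arrays for Adgrf1. The largest falls were in Adgrf1 (-7.01), Hsd3b5 (-6.67), Tff3 (-4.48) and hepcidin, Hamp (-3.76). Then came the serpins Serpina9 (-3.50) and Serpina4-ps1 (-3.34), adropin, Enho (-3.25), and the vasopressin receptor Avpr1a (-3.07). Of the 12575 genes that passed, 5239 were higher and 7336 lower, and 12024 kept their direction on all 4 slides (no test, since they were called on the same mice).

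Both diet comparisons, which share no mice, called 3925 genes higher and 5403 lower in common and 2 in opposite directions, where independent lists of these sizes would share 972 and 2109. The fold changes of all genes had r = 0.932. Lipid droplet genes rose in 14 of 17 cases and fell in 0 (adjusted p = 4.81e-12, adjusted p = 0.0245 with an estimated correlation). All 20 fibrosis genes rose (adjusted p = 4.81e-12, adjusted p = 0.203 with an estimated correlation). SREBP2 targets fell in 20 of 23 cases and rose in 0 (adjusted p = 3.16e-06, adjusted p = 0.348 with an estimated correlation). The unfolded protein and integrated stress response list passed in these mice, with 14 of 20 members lower and 1 higher, or 15 and 1 when adjusted over the list alone (adjusted p = 0.00915, adjusted p = 0.54 with an estimated correlation). Oxidative phosphorylation (adjusted p = 0.109) and female-biased genes (adjusted p = 0.0626) did not pass here, and neither of them passed the interaction of E171 and diet, while the unfolded protein list did (adjusted p = 4.03e-07, adjusted p = 0.7 with an estimated correlation). The share of calls that were higher was 41.7%, against 51.1% with the deposited table and 71.0% when each group was quantile normalized on its own.

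On the normal diet, no single gene passed the test for E171, with 0 genes called in limma and 958 at an unadjusted p under 0.05. The smallest p belonged to Cdkn1a, the p21 inhibitor of cell division, at -1.40 (SE 0.27, adjusted p = 0.362), with -1.40 to 0.09 over its 3 probes. Next were the N-acetyltransferase-like Nat8f5 (-1.03, adjusted p = 0.785) and Ermp1, a metallopeptidase of the endoplasmic reticulum (-0.38, adjusted p = 0.878, with -0.52 to 0.19 over its 4 probes). On the positive side were Exph5 (0.57), Lbx2 (0.23) and Dbp (1.52, SE 0.43, adjusted p = 0.878), none of which passed. The genes fixed in advance for metal, oxidative, inflammatory and scar responses did not pass. They were the metallothioneins Mt1 (-1.0) and Mt2 (-1.24), heme oxygenase Hmox1 (-0.17), Nqo1 (0.03), the cytokines Tnf (-0.34), Il1b (-0.52) and Ccl2 (-0.88), Col1a1 (-0.19) and the acute phase protein Saa1 (-0.80). The SD was wider in controls than with E171 for Mt1 (1.44 and 0.18) and Saa1 (1.54 and 0.84), but not for Il1b (0.63 and 0.85). For Saa1, control replicate 5 alone stood at 8.76, with the nearest other control at 5.61.

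As groups, 13 lists passed on the normal diet with the preset correlation and 0 with an estimated correlation. Glucocorticoid targets were lower as a group (median -0.55, adjusted p = 1.2e-05, adjusted p = 0.0983 with an estimated correlation), and 2 were lower when adjusted over the list alone. Members include Zbtb16, a zinc finger repressor (-0.95), Cebpd, a C/EBP transcription factor (-0.54), and Errfi1, an inhibitor of EGF receptor signalling (-0.55). Inflammatory genes (median -0.29, adjusted p = 1.2e-05, adjusted p = 0.312 with an estimated correlation) included Cxcl1 (-1.69), Ccl7 (-1.09; well above background on 2 of 8 arrays with E171) and Ccl2, all chemokines, with 2 lower when adjusted over the list alone. Immediate early genes (median -0.30, adjusted p = 7.31e-05, adjusted p = 0.0983 with an estimated correlation) included Fos (-1.02). Controls varied more than E171 mice in Cxcl1 (SD 2.07 and 0.96) and Fos (SD 1.09 and 0.45). Targets of p53 (median -0.10, adjusted p = 0.00279, adjusted p = 0.264 with an estimated correlation) included Cdkn1a on the lower side and the growth arrest gene Gadd45a (0.87) on the other, each past a test adjusted over the list alone. Interferon-stimulated genes were lower as a group (median -0.15, adjusted p = 0.000125, adjusted p = 0.729 with an estimated correlation). So were lipid droplet genes (median -0.15, adjusted p = 0.000302, adjusted p = 0.312 with an estimated correlation; Cidec -0.70, Plin4 -0.52) and acute phase genes (median -0.13, adjusted p = 0.00286, adjusted p = 0.747 with an estimated correlation; Saa2 -0.83). Cell cycle (median -0.11, adjusted p = 0.0145, adjusted p = 0.832 with an estimated correlation) and male-biased lists (median -0.20, adjusted p = 0.005, adjusted p = 0.804 with an estimated correlation; Moxd1 -2.41, well above background on 6 and 5 of 8 arrays) were lower as groups. The erythroid list was lower (median -0.21, adjusted p = 0.0217, adjusted p = 0.729 with an estimated correlation). B cell (median 0.27, adjusted p = 0.00315, adjusted p = 0.264 with an estimated correlation; Ms4a1, CD20, 0.64) and endothelial lists were higher (median 0.11, adjusted p = 0.00154, adjusted p = 0.729 with an estimated correlation), as was the female-biased list (median 0.22, adjusted p = 0.0369, adjusted p = 0.439 with an estimated correlation; Cyp2b9 1.73). In simulated data for the same test on the Western diet, 55.2% of genes moved by 0.5 were called at this number of mice. Of genes moved by 1, 92.5% were called. These shares do not carry over to the normal diet. In the simulation many genes were moved at once, which eases the adjusted threshold, and noise was independent between genes. Cdkn1a (-1.40) and Dbp (1.52) did not pass, so the lack of calls on the normal diet does not exclude differences of this size.

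On the Western diet, Zbtb16, Hspa1a and Cdkn1a were among the genes with lower mRNA in E171 mice than in controls. Zbtb16, a zinc finger repressor induced by glucocorticoids (chromosome 9, 48462419 to 48462478, mm9), fell by 2.16 (SE 0.33, adjusted p = 0.0013), which is 4.48-fold lower. The inducible HSP70 chaperones Hspa1b and Hspa1a fell by 1.86 (adjusted p = 0.00933) and 1.60 (SE 0.26, adjusted p = 0.00355), Igfbp1, an IGF-binding protein, by 1.72 (SE 0.38, adjusted p = 0.0348), and Cdkn1a by 1.33 (SE 0.27, adjusted p = 0.0246, with -1.42 to -0.85 over its 3 probes). The replication-dependent histones H2bc23 (-2.05, SE 0.36, adjusted p = 0.00721) and H3c8 (-1.55, adjusted p = 0.0013) and the noncoding RNA Lockd (-1.23) fell as well. Among genes with a symbol, the largest rise was in Cd163l1, a scavenger receptor of the CD163 family (1.95, SE 0.29, adjusted p = 0.0013, no overlap between the groups). Other rises were those of Casz1, a zinc finger factor (1.05, adjusted p = 0.00576, with 0.31 to 1.05 over its 4 probes), and Slc2a5, the fructose transporter (0.99, adjusted p = 0.0348). Smaller rises were those of Lrrc4c, a synaptic adhesion protein (0.86), Pomc, the precursor of ACTH (0.72, adjusted p = 0.0246), and Fhdc1, a formin (0.71). In the dimmer group the probe was well above background on 2 of 8 arrays for Cd163l1, 2 for H2bc23 and 1 for H3c8 (7 in the other group).

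**Figure D2:**
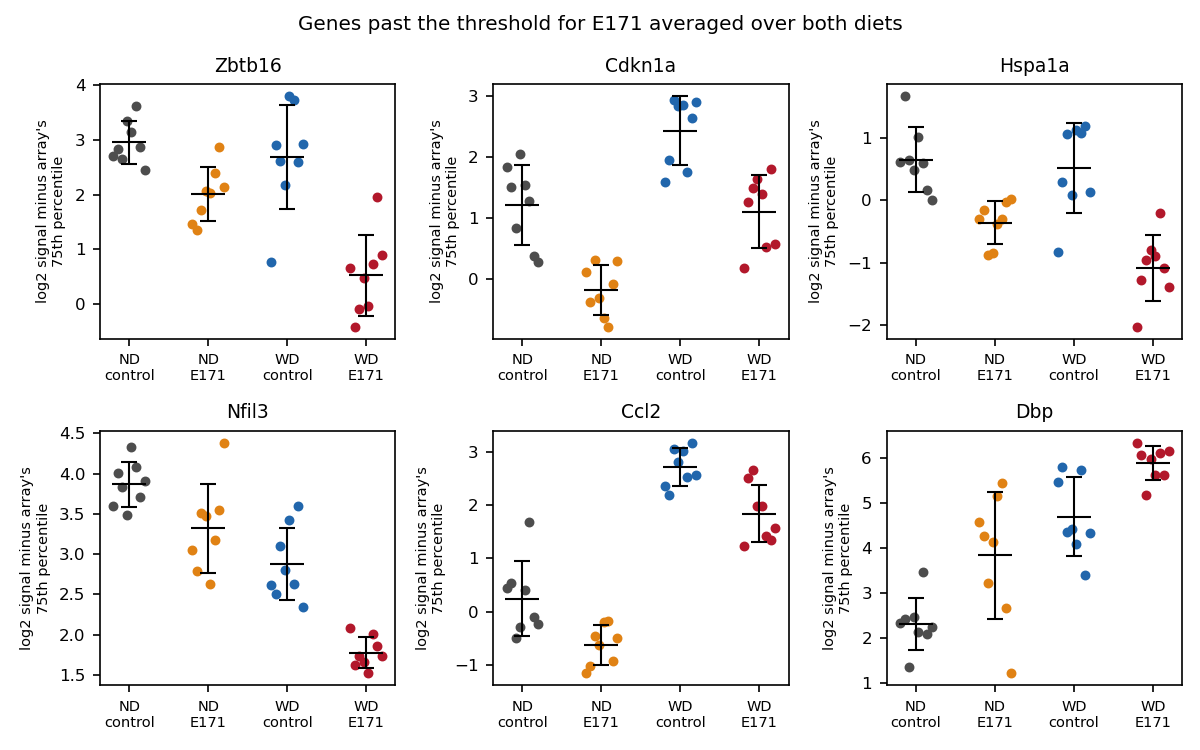
Log2 values of 6 genes, relative to the 75th percentile of each array, in the 4 groups; points are mice and bars show the mean ± SD of 8 mice. ND, normal diet; WD, Western diet; Nfil3 was chosen after its values were seen.

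In all, 90 genes passed, 50 higher and 40 lower, and 89 of them kept their direction on all 4 slides. The genes were called on the same mice, which nearly fixes this count in advance, so it is no test. Without Western diet control replicates 5 and 6, the arrays with the lowest correlation to their group, 101 genes passed (39 higher, 62 lower), 42 of them shared with the 90. The share of higher calls was 55.6%, against 46.5% with quantile normalization, 37.3% with the deposited table and 7.10% when each group was quantile normalized on its own. Of the genes named here, Zbtb16, Hspa1a and Cd163l1 kept their call in each setting that measured them, of the 14 in which single genes were followed, while Lrrc4c lost its call in 6 of them, Pomc and Cebpd in 4 each, and H2bc23, Igfbp1, Slc2a5, Fhdc1 and Trp53inp1 in 2 each. Cdkn1a, Hspa1b, Casz1 and Lockd lost it in the fit of only the groups of the contrast, and H3c8 with normexp. Lrrc4c, Pomc, Cebpd, Fhdc1 and Trp53inp1 lost it without those 2 mice.

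Of the lists, 10 passed, 2 of them also with an estimated correlation. Glucocorticoid targets were lower (median -0.56, adjusted p = 3.31e-09, adjusted p = 0.0075 with an estimated correlation). Zbtb16 and Cebpd (-0.67, adjusted p = 0.039) of the 10 measured passed over all genes, and 6 passed when adjusted over the list alone. Tsc22d3, the glucocorticoid-induced leucine zipper, stood at -0.87 (adjusted p = 0.0816). Targets of p53 were lower (median -0.23, adjusted p = 3.63e-07, adjusted p = 0.0111 with an estimated correlation). Cdkn1a and Trp53inp1, a p53-induced stress protein (-0.82, adjusted p = 0.0342), passed over all genes, and 6 of 17 when adjusted over the list alone, including Eda2r (-1.01) and Btg2 (-0.69). Cell cycle genes were lower as a group (median -0.48, adjusted p = 3.77e-08, adjusted p = 0.47 with an estimated correlation). Of its 21 members 0 passed over all genes and 8 were lower when adjusted over the list alone, among them Cdk1 (-0.94), Ccnb2 (-0.90) and Birc5 (-0.78). Without Western diet control replicates 5 and 6, Cdk1 (-1.40, adjusted p = 0.0129), Ccnb2 (-1.29, adjusted p = 0.000434) and Birc5 (-1.06, adjusted p = 0.0103) passed over all genes, as they did with array weights. These 2 settings are not separate, since both mice had low array weights (0.39 and 0.46). Of the Western-diet mice they lay nearest to the normal-diet mice on the first principal component (2.98 and 19.1). Cell cycle genes rose with the diet and no E171 mouse was left out, so leaving these controls out can by itself widen the difference. The unfolded protein and integrated stress response (median -0.35, adjusted p = 8.14e-08, adjusted p = 0.47 with an estimated correlation) had 4 of 20 lower when adjusted over the list alone. Among them were Chac1, which degrades glutathione (-0.98), the stress factor CHOP, Ddit3 (-0.84), and the chaperone Dnajb9 (-0.64). B cell markers were higher (median 0.38, adjusted p = 0.000569, adjusted p = 0.148 with an estimated correlation). When adjusted over the list alone 4 of 8 passed, among them the antigen receptor chains Cd79a (0.53; well above background on 5 and 7 of 8 arrays) and Cd79b (0.51). Interferon-stimulated genes (median -0.12, adjusted p = 0.000345, adjusted p = 0.702 with an estimated correlation; Rsad2 -0.66, Oas2 -0.48) and inflammatory genes (median -0.21, adjusted p = 0.00876, adjusted p = 0.702 with an estimated correlation; Ccl7 -0.98, Ccl2 -0.87) were lower as groups. NRF2 targets (median -0.08, adjusted p = 0.0159, adjusted p = 0.643 with an estimated correlation; Gsta2 -0.66) and amino acid genes (median -0.17, adjusted p = 0.0159, adjusted p = 0.914 with an estimated correlation; tyrosine aminotransferase, Tat, -0.71) were lower too. The same was found for immediate early genes (median -0.23, adjusted p = 0.0204, adjusted p = 0.47 with an estimated correlation; Klf6 -0.50). Mt1 (-0.16), Mt2 (-0.38), Hmox1 (-0.34, adjusted p = 0.258), Nqo1 (-0.15), Tnf (-0.13), Il1b (0.03), Ccl2 (adjusted p = 0.0989), Col1a1 (0.14) and Saa1 (-0.02) did not pass.

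Averaged over both diets, Cdkn1a, Hspa1a and Zbtb16 were lower with E171, and the clock gene Dbp was higher. Cdkn1a fell by 1.37 (SE 0.19, adjusted p = 0.000774), Hspa1a by 1.30 (SE 0.18, adjusted p = 0.000774) and Zbtb16 by 1.55 (SE 0.23, adjusted p = 0.00121). The value of Cdkn1a is that of its probe with the highest mean signal, and another of its probes did not fall on the normal diet. Igfbp1 (-1.33, adjusted p = 0.0197), H2bc23, Hspa1b (-1.18, adjusted p = 0.021), the monocyte chemokine Ccl7 (-1.04, adjusted p = 0.0131) and the phosphatidate phosphatase Lpin1 (-0.91, adjusted p = 0.0416) completed the largest falls. Dbp, a transcription factor driven by the circadian clock (chromosome 7, 52965265 to 52965324, mm9), rose by 1.35 (SE 0.30, adjusted p = 0.0365). Other rises were those of Cd163l1, the olfactory receptors Olfr978 (0.79) and Olfr885 (0.59), Fbxw22, an F-box protein (0.52), and Ripor2, a cell polarity protein (0.52). Smaller ones were those of Cd180, a toll-like receptor homologue of B cells (0.47, adjusted p = 0.0331, with -0.01 to 0.47 over its 4 probes), and tissue factor, F3 (0.46, adjusted p = 0.0372). For H2bc23 and Cd163l1 no averaged value is given, since the probe was well above background on 0 of 16 normal-diet arrays. For Ccl7 it was so on 2 of 8 normal-diet arrays with E171, and for Fbxw22 on 5, 8, 4 and 7 of 8 arrays in normal diet control, normal diet E171, Western diet control and Western diet E171. Passing genes numbered 87, 44 higher and 43 lower, all 87 with 1 direction on all 4 slides, which is no test since they were called on the same mice. Without Western diet control replicates 5 and 6 there were 97, of which 63 were shared, and Ripor2, Cd180, F3, Lpin1, Btg2 and Oas2 lost their call. Over the settings in which single genes were followed, Fbxw22 lost its call in 7, Btg2 in 6, Olfr978 and Ripor2 in 5 each, F3 and Oas2 in 4 each, Cd180 in 3 and Lpin1 in 2. Dbp and Olfr885 lost it without a filter on dim probes, and Ccl7, H2bc23 and Cd163l1 with normexp. The share of higher calls was 50.6%, against 27.7% with the deposited table, 36.1% without those mice and 5.21% when each group was quantile normalized on its own.

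Across both diets 11 lists passed, 3 of them also with an estimated correlation. These 3 were glucocorticoid targets (median -0.57, adjusted p = 2.92e-11, adjusted p = 0.00221 with an estimated correlation) and p53 targets (median -0.11, adjusted p = 1.78e-07, adjusted p = 0.00801 with an estimated correlation) on the lower side, and B cell markers (median 0.34, adjusted p = 2.77e-05, adjusted p = 0.0473 with an estimated correlation). Of the 10 glucocorticoid targets 3 fell, Zbtb16, Cebpd (-0.61, adjusted p = 0.00774) and Lpin1, and 8 when adjusted over the list alone. Of the 17 p53 targets 3 fell, Cdkn1a, Trp53inp1 (-0.62, adjusted p = 0.0215) and Btg2 (-0.64, adjusted p = 0.0474, and adjusted p = 0.102 without Western diet control replicates 5 and 6), with 8 lower and 1 higher when adjusted over the list alone. Inflammatory genes were lower as a group, with Ccl7 and Ccl2 (-0.87, adjusted p = 0.0185) past the test and 5 lower when adjusted over the list alone (median -0.24, adjusted p = 6.87e-06, adjusted p = 0.412 with an estimated correlation). Interferon-stimulated genes were lower too, with Oas2 (-0.45, adjusted p = 0.0404) and 8 lower when adjusted over the list alone (median -0.14, adjusted p = 1.41e-06, adjusted p = 0.563 with an estimated correlation). Cell cycle (median -0.32, adjusted p = 4.74e-08, adjusted p = 0.421 with an estimated correlation) and immediate early lists (median -0.27, adjusted p = 3.75e-05, adjusted p = 0.0524 with an estimated correlation) were lower as groups. So were the unfolded protein (median -0.09, adjusted p = 0.000527, adjusted p = 0.564 with an estimated correlation) and acute phase lists (median -0.10, adjusted p = 0.00171, adjusted p = 0.655 with an estimated correlation). The amino acid (median -0.09, adjusted p = 0.00969, adjusted p = 0.831 with an estimated correlation) and NRF2 lists (median -0.06, adjusted p = 0.0167, adjusted p = 0.564 with an estimated correlation) were lower as groups. Mt1 (-0.58), Mt2 (-0.81), Hmox1 (-0.25), Nqo1 (-0.06), Tnf (-0.23), Il1b (-0.25), Col1a1 (-0.03) and Saa1 (-0.41) did not pass.

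Between the diets, the E171 differences of single genes were not shown to differ. In limma 0 genes passed the interaction of E171 and diet, and 1222 had an unadjusted p under 0.05. The smallest p values were those of the calcium channel subunit Cacng7 (0.67), Pced1b (0.61) and calsyntenin Clstn3 (1.26) on the higher side. On the lower side they were those of H3c8, which was well above background on 0 of 16 normal-diet arrays, so that no value is given, the ceramide glucosyltransferase Ugcg (-0.45) and the histone H4c9 (-0.70), and the smallest adjusted p was 0.332. Over 2 probes each, Cacng7 ran from 0.20 to 0.67 and Clstn3 from 0.33 to 1.26, and Ugcg over 4 from -0.45 to -0.29. Zbtb16, at -1.22, had an interaction p of 0.0131 and an adjusted p of 0.918. Over all genes, the E171 differences on the normal and on the Western diet, which come from separate mice, had r = 0.241, and 57.1% of genes had the same sign in both. Among 100 random relabellings within each diet r ran from -0.28 to 0.29 (permutation one-sided p = 0.02, permutation two-sided p = 0.05).

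As groups, 6 lists passed the interaction with the preset correlation and 0 with an estimated correlation. The unfolded protein and integrated stress response was lower with E171 on the Western than on the normal diet (median -0.46, adjusted p = 4.03e-07, adjusted p = 0.7 with an estimated correlation), with Creld2 (-0.90), Manf (-0.70) and Ddit3 (-0.64). The other probe of Ddit3 stood at 0.06. Lower too were cell cycle genes (median -0.13, adjusted p = 0.00491, adjusted p = 0.892 with an estimated correlation; Ccnb2 -0.94; Cdk1 -1.20, with its probe well above background on 1 of 8 arrays in each normal-diet group) and glucocorticoid targets (median -0.21, adjusted p = 0.0382, adjusted p = 0.7 with an estimated correlation). The p53 targets had the same direction (median -0.10, adjusted p = 0.0387, adjusted p = 0.7 with an estimated correlation). The lipid droplet list was higher (median 0.25, adjusted p = 0.0071, adjusted p = 0.7 with an estimated correlation), with Cidea (2.15), Fitm1 (0.89), Cidec (0.87) and the adipogenic receptor Pparg (0.68). The erythroid list was higher as well (median 0.57, adjusted p = 0.00176, adjusted p = 0.7 with an estimated correlation), with the anion exchanger Slc4a1 (0.66) and the globin Hbb-bt (0.60).

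Scores per mouse, the mean of the members of a list after centring each gene, were added after the list results had been seen, together with a clock score, the mean of day genes minus the mean of night genes. They were picked after the gene and list results on the same mice and adjusted over the 16 chosen tests only, so their p values are no separate support. The glucocorticoid score was lower with E171 on the normal diet (-0.42, exact two-sided p = 0.00109, adjusted p = 0.00559 over 16 tests) and on the Western diet (-0.72, exact two-sided p = 0.000622, adjusted p = 0.00559). Each had 1 direction on all 4 slides, which is no test for the same reason. The p53 score was lower as well (-0.16, exact two-sided p = 0.00544, adjusted p = 0.0145, and -0.31, exact two-sided p = 0.000932, adjusted p = 0.00559). The B cell score was higher by 0.26 (exact two-sided p = 0.0392, adjusted p = 0.0696) and 0.36 (exact two-sided p = 0.0014, adjusted p = 0.00559). Immediate early scores were at -0.34 (exact two-sided p = 0.00948, adjusted p = 0.0217) and -0.25 (exact two-sided p = 0.0503, adjusted p = 0.0806). The clock score was higher by 0.77 (exact two-sided p = 0.0676, adjusted p = 0.0983) on the normal diet and by 1.03 (exact two-sided p = 0.00311, adjusted p = 0.00995) on the Western diet. Cell cycle scores were at -0.11 (exact two-sided p = 0.211) and -0.41 (exact two-sided p = 0.0847). Inflammatory scores were at -0.34 (exact two-sided p = 0.0267, adjusted p = 0.0535) and -0.22 (exact two-sided p = 0.229), with interferon scores at -0.13 (exact two-sided p = 0.339) and -0.17 (exact two-sided p = 0.237).

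**Figure D3:**
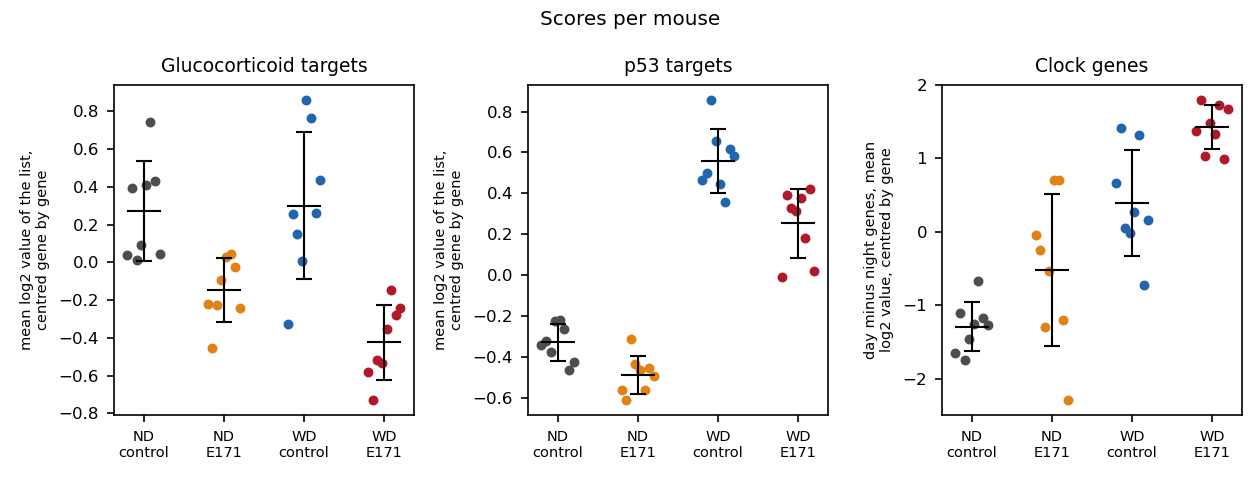
Scores of 3 gene lists per mouse (points), on the log2 scale and centred gene by gene, in the 4 groups, with the mean ± SD of 8 mice as bars. ND, normal diet; WD, Western diet; the clock score is the mean of day genes minus the mean of night genes, and all scores were chosen after the gene results had been seen.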

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

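All tests of explanations in this part were chosen after the results they address had been seen, with an exception. The test of the clock shift as the whole cause, for E171 averaged over both diets, was written down before its result. The random splits were planned, but their criterion was also written after the counts were known. The rule that a covariate decides nothing if it moves no called difference by 0.5 of the median called difference was also added after the values had been seen.

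Random splits of the same mice into groups of the same sizes, 100 per contrast with the real one included, show which counts of genes chance could give. For the Western diet, only 1 split (the real one) reached 11183 genes in controls and 1 reached 12575 in E171 mice. The highest of the other splits called 3927 and 6439, so chance between single mice is excluded as far as 100 splits can show. The same holds for the 87 genes of E171 averaged over both diets (1 split, highest other 8), again only for chance between single mice. Litters are not known in any group, and E171 followed the treatment of the mother, so these splits cannot exclude a chance difference between litters. For the 90 genes of E171 on the Western diet chance is not excluded, since 5 splits called as many. The highest other called 1691, while the median of the other splits was 0, and why some splits called so many was not shown. With 0 genes called for E171 on the normal diet and for the interaction, all 100 splits were as large, with 118 and 110 as the highest others. In camera with the preset correlation, as many lists passed in 6 splits for the diet in controls (real 23, highest other 27) and 7 in E171 mice (22 and 23). This cannot decide whether the diet lists exceed chance, since splits with unequal numbers of Western-diet mice still carry part of the diet effect. For E171, as many lists passed in 15 splits on the normal diet (13 and 17), 80 on the Western diet (10 and 21) and 53 averaged (11 and 20). For the interaction it was 90 splits (6 and 19). The list counts of E171 and of the interaction are thus not above chance.

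The first pattern is the set of 87 genes called for E171 averaged over both diets, with Zbtb16, Hspa1a and Cdkn1a on the lower side. Each slide held 2 mice of every group, so a difference between slides adds alike to all groups, and 83 of the 87 were also called with slide as a block. An unequal strength of the diet response between mice stays open: 100% of the genes kept at least 0.5 of their difference with the place of each mouse on the main mouse to mouse axis as a covariate, but this decides nothing, since the axis hardly differs with E171 and moved no called difference by more than 0.0231. An earlier form of this test, with the first component of the residuals, was void because the component is centred within groups. Without Western diet control replicates 5 and 6, 63 of the 87 stayed called. A shift of the clock phase at sampling cannot be told apart from an effect of E171, because the clock score was higher with E171 by 1.03 on the Western diet (exact two-sided p = 0.00311) and 0.77 on the normal diet (exact two-sided p = 0.0676) and the labels give no time of sampling. As the whole cause, the clock shift is argued against only so far as the clock score captures it. With the score as a covariate 95.4% of the genes (83 of 87) kept at least 0.5 of their difference, but a score measured with error can correct too little. Zbtb16 stood at -1.55 (SE 0.23) before and -1.57 (SE 0.29) after, but Cdkn1a at -1.37 (SE 0.19) before and -0.97 (SE 0.21) after. Dbp, itself in the score, moved most, from 1.35 to 0.21. Only 5 of the 87 stayed called, since the differences shrank to a median of 87.7% and the standard errors grew. Handling, litter and E171 itself stay open.

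The second pattern is the 90 genes called for E171 on the Western diet. Because some other splits called many genes, an unequal strength of the diet response was tested. E171 and control mice did not show a detectable difference on the mouse to mouse axis (2.91, 95% interval -27.9 to 33.8, exact two-sided p = 0.842, with a diet shift of 55.7 in controls). With the axis as a covariate 100% of the 90 genes kept at least 0.5 of their difference. This decides nothing, since the covariate moved no called difference by more than 0.0681 and the interval reaches over 0.5 of the diet shift. The 2 Western-diet mice lowest on the first principal component, control replicates 5 and 6 (2.98 and 19.1), bear on the calls, with 42 of the 90 still called without them. Array intensity as a covariate left 100% of the 90 called, but moved no called difference by more than 0.217 (median called difference 0.62 in size), so it decides nothing either. The clock score was higher with E171 by 1.03 on this diet (exact two-sided p = 0.00311). With it as a covariate 100% of the 90 kept at least 0.5 of their difference (median 90.4%), but only 4 stayed called. A score measured with error can correct too little, and the labels give no time of sampling. Unequal diet response, array intensity, a shift of the clock phase and, for the count, chance stay open, and litter was not tested.

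The third pattern is the rise of macrophage and scar genes on the Western diet. A lower share of hepatocytes would raise the markers of every other cell type alike; the endothelial score differed by -0.0355 in controls (95% interval -0.22 to 0.15), while the lipid-associated macrophage score rose by 2.51 (95% interval 1.85 to 3.17) and the hepatocyte score fell by 0.41. Differences nearer in size to the hepatocyte fall were those of the Kupffer cell (0.60), cholangiocyte (0.67), neutrophil (0.46), T and NK cell (0.41), stellate cell (0.34) and B cell scores (0.15), with the erythroid score at -0.19. Because endothelial and lipid-associated macrophage scores moved apart by more than their spread, this argues against a lower hepatocyte share as the whole account, and a part played by it stays open. More macrophages or higher expression in each of them stay open, and neither was tested.

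Of 264 tests for a mouse far from the other 7 of its group (64 named genes and 2 array measures in 4 groups), 16 met the criterion, where chance gives about 5%. Normal diet E171 replicate 6 met it 4 times: lowest for Cnmd (-0.77, nearest other -0.09), highest for H2bc23 (-6.62, nearest -7.28) and Clstn3 (2.15, nearest 1.40), and lowest 75th percentile of intensity (249, nearest 329). Normal diet control replicate 5 also met it 4 times: highest for Saa1 (8.76, nearest 5.61) and Cd163l1 (-6.02, nearest -6.92), lowest for Lrrc4c (-4.51, nearest -3.54), and fewest probes well above background (33697, nearest 34807). Normal diet control replicate 4 was highest for Sdcbp2 (-4.15, nearest -4.74) and lowest for Serpina9 (-2.75, nearest -1.11). Gpnmb, H2bc23 and Cd163l1 were well above background on 0 of 16 normal-diet arrays, so their values there lie at the background. In other normal-diet mice these were Gpnmb in E171 replicate 3 (-6.05, nearest -6.88), Pomc in E171 replicate 2 (-2.22, nearest -3.05) and Lbx2 in control replicate 1 (-1.92, nearest -1.80). On the Western diet these were Exph5 in control replicate 5 (-3.89, nearest -4.53), Mt1 in control replicate 6 (7.51, nearest 6.05), and the number of probes well above background in E171 replicate 8 (32163, nearest 35029).

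The difference between the E171 effects on the Western and the normal diet passed the interaction test for 6 lists: lipid droplet and lipid uptake (median 0.25), unfolded protein and integrated stress response (-0.46), cell cycle (-0.13), p53 targets (-0.10), glucocorticoid targets (-0.21) and erythroid cell (0.57). None of these 6 passed with an estimated correlation or with fry.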

How the results depend on the processing

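The quantile normalizations of the median signal, the fit without the 2 arrays of lowest correlation and the fits with a covariate were added after seeing the data; the other settings were planned. In the 14 settings in which single genes were followed, no named gene passed in opposite directions. On the normal diet, however, other probes of Cdkn1a (up to 0.09) and Ermp1 (up to 0.19) had the other sign for E171. The other probe of Ddit3 (0.06) had the other sign for the interaction. For the diet, 8041 to 9765 genes were shared between controls and E171 mice over the settings, and the correlation of the E171 effects in both diets ran from 0.14 to 0.32. Gene counts not given here stayed within 1.5 times the main ones, and the cause of a change was not tested unless it is given.

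With a fold change of at least 1.5, which removes small changes by construction, the counts were 3948 and 4562 for the diet in controls and E171 mice, 49 for E171 on the Western diet (main 90) and 28 averaged (main 87). With array weights E171 gave 174 and 157 genes (78 and 86 shared with the main calls), with array intensity as a covariate 194 and 189, and with the first residual component 397 and 391, which lowers the residual spread by construction. With the mouse to mouse axis, which itself differs between the diets, the diet counts were 4970 and 6060, and E171 gave 297 and 320. With the clock score as a covariate E171 gave 4 and 7 genes, since differences shrank and standard errors grew, and the diet 8789 and 8918. A fit of only the groups of the contrast, with fewer mice, gave 38 genes for E171 on the Western diet (27 higher, 11 lower). Without a filter on dim probes, with more genes tested, the averaged count was 43 and the interaction had 1 gene.

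Replicate numbers were not taken to pair the mice, though same-numbered mice were somewhat more alike: 23 of 48 such pairs had a correlation of deviations above 0.1 (median 0.0683, against -0.0185 for other pairs), 10 of 19 on the same slide and 13 of 29 on other slides, against 24 of 77 and 50 of 259 of other pairs. Of 32 mice 8 correlated best with their own number. With replicate number as a block E171 gave 93 genes higher and 78 lower on the Western diet (1.7e+02 in all), 149 averaged over both diets, and 1 for the interaction.

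Quantile normalization within each group, which leaves the groups on separate scales, moved the median of all genes from -0.10 to 0.10 (diet in controls) and to -0.08 for E171 on the Western diet; E171 then gave 1183 genes (84 higher, 1099 lower; 79 shared with the main calls) and averaged 710 (37 and 673; 66 shared). The share of higher diet calls, 39.2% and 41.7%, was 31.2% and 37.4% with normexp and 45.5% and 44.8% with quantile normalization. The median of the list oxidative phosphorylation, Western against normal diet in controls, -0.15, reversed to 0.0629 with quantile normalization, 0.0650 with the deposited table, 0.0668 with the median signal quantile normalized over all arrays and 0.0877 within each group.

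Lists depended most on the test. With an estimated correlation 2, 1, 0, 2, 3 and 0 lists passed (diet in controls, diet in E171 mice, E171 on the normal diet, on the Western diet, averaged, interaction), against 23, 22, 13, 10, 11 and 6. With fry the diet had 25 lists in controls and 31 in E171 mice, and in each case 22 of these were among the main ones with the same direction. In the same test E171 had 0 lists on the normal diet, 3 on the Western diet and 4 averaged, and the interaction 0. The interaction had 10 lists with normexp and 10 without the 2 arrays of lowest correlation. Signal well above background on 32163 to 37261 probes per array limits what can be said of dim genes.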

Other observations

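Most, but not all, day genes of the circadian clock stood higher and most night genes lower with E171 and with the Western diet, while the fixed clock list, which holds both kinds, did not pass (adjusted p = 0.702 for the diet in controls); the clock score and its tests were chosen after the gene results had been seen, and so were all genes in this part. Averaged over both diets, 9 of 10 day genes were higher with E171, including Dbp (1.35, adjusted p = 0.0365), Ciart (0.91), Per3 (0.84), Tef (0.52) and Hlf (0.37), of which Dbp alone passed, and the exception was Per1 (-0.54), a clock gene that also responds to glucocorticoids. Of the night genes 4 of 5 were lower, including Nfil3, a repressor that competes with Dbp for its sites (-0.82, adjusted p = 0.00256), and Arntl, BMAL1 (-0.82, adjusted p = 0.0582). The Western diet went with a difference in the same direction, with the clock score higher by 1.68 in controls (exact two-sided p = 0.000311) and by 1.95 in E171 mice (exact two-sided p = 0.000155), Dbp at 2.39, Cry1, a clock repressor, at -1.12 and Arntl at -1.33 in controls. Against this direction, the day gene Hlf was lower in controls (-0.42, adjusted p = 0.0375), and Hlf (-0.10) and Nr1d1 (-0.35) stood lower in E171 mice without passing. The differences with E171 were 0.77, -0.06, 1.69 and 0.66 on the 4 slides on the normal diet and 0.61, 0.95, 1.16 and 1.42 on the Western diet.

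Over the 32 mice, after removing group means, the clock score had r = 0.27 with the glucocorticoid score (permutation two-sided p = 0.143; 0.58, -0.20, 0.67 and 0.39 on the 4 slides) and r = -0.34 with the p53 score (permutation two-sided p = 0.0419, adjusted p = 0.126 over 3 relations; -0.51, -0.44, -0.58 and -0.39 on the slides). With the cell cycle score r was -0.25 (permutation two-sided p = 0.177). None of these passed the adjustment.

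Thbd, thrombomodulin (-0.52, adjusted p = 0.01), Jdp2 (-0.51, adjusted p = 0.0082) and Fosl2 (-0.57, adjusted p = 0.0185), AP-1 factors, Nfkb2, an NF-kB subunit (-0.31, adjusted p = 0.0294), the chaperone Dnajb1 (-0.59, adjusted p = 0.021) and the carboxylesterase Ces1a (-0.88, adjusted p = 0.0132) fell averaged over both diets. Of these, Ces1a had risen with the Western diet in controls by 3.61.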
